A study of Badhamia polycephala with 3 samples.

How the data were processed

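Poly(A) RNA from macroplasmodia of Physarum (listed by GEO as Badhamia polycephala), a slime mould whose macroplasmodium is a single giant cell with many nuclei, was sequenced in 3 libraries with 1 library per group. Per the labels' protocols, the RNA was treated with phosphatase and pyrophosphatase so that an adapter was ligated to the 5' end of decapped mRNA, cDNA was primed with random hexamers and amplified by 22 cycles of PCR with a 4-bp barcode for each library, the cDNAs were pooled in equivalent amounts, and fragments of 250 to 450 bp were sequenced on an Illumina instrument. The labels mention no molecular identifiers, so reads from 1 amplified molecule cannot be told from reads of several. A read starts at or near the 5' end of an mRNA in this design, and its count on a contig was therefore not divided by contig length.

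The deposited values are raw read counts per contig, per the file headers, with the same 94186 contig IDs in each library. Bowtie and SAMtools are named without versions, per the submitters' processing notes. The assembly that the contigs belong to, the settings of the alignment and the handling of reads that align to more than 1 contig are not given in the sources used here. Contig IDs carry 1 of 3 prefixes (ctg, rep and vbc), whose meaning is not given there either. The files do not pair contig IDs with gene names and no genome or annotation was used here, so contigs are named by their IDs, without gene function, position or exon structure, and the 26 lists of gene functions prepared for this tissue were not run. If several contigs hold pieces of 1 transcript, or near-identical copies of it, the aligner could have split its reads among them.

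Totals were 1038237 reads in the starved library, 562885 in the 2 h library and 785984 in the 6 h library. Contigs with at least 20 reads summed over the 3 libraries entered the comparisons, which left 2608 contigs holding 97.3% of all reads. Counts were scaled by library totals multiplied by TMM factors from edgeR 4.0.16 in R 4.3.3, computed on these 2608 contigs, which were 0.917 for the starved, 1.09 for the 2 h and 1.00 for the 6 h library. Values below are given as CPM, counts per 1000000 reads of the scaled total.

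With 1 library per group there is no estimate of the spread between cultures, so no difference between libraries has a replicate check and no p-value is given. For each contig and pair of libraries the ratio of scaled counts was given the exact (Clopper-Pearson) 95% interval of its share of the reads of both libraries, with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. A contig was called higher when the lower limit of its ratio was above 2 and lower when the upper limit was below the inverse of 2. Such a call compares 2 libraries, not 2 conditions. Intervals and limits of ratios and shares cover counting error only. A fold against a library with 0 reads is given as a lower bound against a floor of 3 reads in that library, which corresponds to 2.89 CPM in the starved, 5.33 in the 2 h and 3.82 in the 6 h library before TMM scaling. Correlations across contigs used log2(CPM + 1), with intervals from 1000 bootstrap draws of contigs. The bootstrap intervals measure the spread across contigs, which are not replicates.

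Calls from counting error alone were estimated from 100 simulated sets of 3 libraries drawn from the pooled profile at the real totals. The calling step was tested on simulated data for 2608 contigs, 200 of them changed. For the 2 h against the starved library it called 72.0% of 4-fold rises, 100% of 16-fold rises, 16.0% of 4-fold falls and 54.0% of 16-fold falls, with 1 call among 2408 unchanged contigs. For the 6 h against the starved library the shares were 78.0%, 100%, 44.0% and 62.0%, and for the 6 h against the 2 h library they were 48.0%, 100%, 22.0% and 40.0%, with 0 calls among unchanged contigs in both. Falls were therefore recovered less often than rises of the same size. The simulated reads carried counting error only and the calling step was given their true scaling. The test therefore covers neither the TMM scaling nor uneven amplification.

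Contigs named in the text were, for each comparison, the 2 called higher with the highest lower limit of the ratio and the 2 called lower with the lowest upper limit; other contigs named were chosen after their values were seen, and the text says so. The groups, the calling rule, the naming rule and the alternatives were fixed before the data were examined, except where the text says that a choice was made afterwards. The alternatives were scaling by total counts or by DESeq2 1.42.0 size factors, no filter or a minimum of 100 reads, a 99% interval, a fold limit of 4, removal of the 10 most abundant contigs of each library, thinning of every library to 562885 reads, and a pseudocount of 10 CPM. The division of contigs by ID prefix, the division of reads by the median reads per contig, and the comparison of the starved and 6 h libraries alone were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9.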

Results

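Transcripts of Physarum macroplasmodia were counted in 3 libraries. The starved library came from a plasmodium starved for 6 h. The 2 h library came from a plasmodium that was starved for 6 h, exposed to far-red light for 30 min and kept in the dark without food for another 2 h. The 6 h library came from a starved plasmodium taken 6 h after photoinduction by light; its label gives neither the length of starvation nor the wavelength or length of the exposure, so it is not stated that these matched those of the 2 h library. Far-red light is a known trigger of sporulation in starved plasmodia of this species. The design asks how transcript levels differ between the starved state and each time after photoinduction. Read totals were 1038237 in the starved library, 562885 in the 2 h library and 785984 in the 6 h library. Each state was represented by 1 library, so every difference below is between libraries and has no replicate check. Intervals of folds and shares cover counting error only, and those of correlations and covariances cover the spread across contigs.

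The libraries differed in how many contigs they contained. Reads fell on 11315 contigs in the starved library, 3076 in the 2 h library and 8849 in the 6 h library, out of 94186 listed. After each library was thinned to 562885 reads, the counts were 9347 in the starved and 8227 in the 6 h library, both still above the 3076 of the 2 h library. Contigs with 5 or more reads at these equal totals numbered 2576 in the starved, 2972 in the 6 h and 2194 in the 2 h library. Of the 16331 contigs with at least 1 read in any library, 1377 had reads in all 3, 6046 in the starved library only, 882 in the 2 h library only and 3871 in the 6 h library only. A contig with reads had a median of 3 reads in the starved library, 9 in the 2 h library and 4 in the 6 h library. Contigs seen with a single read made up 26.5% of the contigs with reads in the starved library, 9.30% in the 2 h library and 18.5% in the 6 h library.

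**Figure D1:**
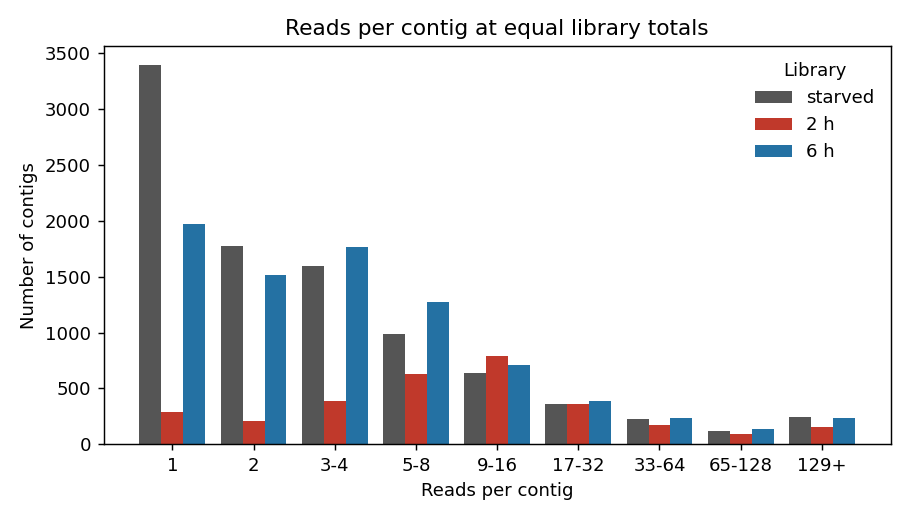
Number of contigs (vertical axis) by reads per contig (horizontal axis, in bins that widen to the right) in the starved, 2 h and 6 h libraries after thinning each to 562885 reads. Single-read contigs numbered 3396 in the starved, 286 in the 2 h and 1973 in the 6 h library, whereas 641, 789 and 711 contigs had 9 to 16 reads.

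A few contigs held a large share of the reads in each library. The 10 most abundant contigs took 47.8% of the reads (95% exact binomial interval 47.7 to 47.9) in the starved library, 67.9% (67.8 to 68.0) in the 2 h library and 53.3% (53.2 to 53.4) in the 6 h library. The most abundant single contig was ctg7802 in the starved library with 14.3% of reads (14.3 to 14.4), ctg8463 in the 2 h library with 25.4% (25.3 to 25.5) and ctg4632 in the 6 h library with 11.0% (10.9 to 11.1). Among the 10 most abundant of each library, 2 contigs were common to all 3. The share of ctg4632 was 2.69% in the starved, 7.23% in the 2 h and 11.0% in the 6 h library, and that of ctg5859 was 3.83%, 9.98% and 8.24%. ctg4632 and ctg5859 are named because they were the contigs common to these sets, a choice made after their values were seen. Of the 100 most abundant contigs in each library, 37 were shared by the starved and 6 h libraries, 30 by the starved and 2 h libraries, 29 by the 2 h and 6 h libraries and 20 by all 3.

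Contigs with the prefix ctg held 92.1% of reads in the starved library, 82.5% in the 2 h library and 87.4% in the 6 h library. Contigs with the prefix rep held 6.66%, 16.4% and 10.7%, and those with the prefix vbc held 1.22%, 1.05% and 1.87%. The exact binomial intervals of these shares did not overlap between any pair of libraries, but they treat amplified reads as independent and cover counting error only. The division by prefix was made after the data were seen. A single contig, rep42, had 1298 reads in the starved, 51257 in the 2 h and 1628 in the 6 h library, and without it the rep contigs held 6.54%, 8.07% and 10.6%, so that the 6 h library ranked highest; rep42 was named after its values were seen.

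Across the 2608 contigs with at least 20 reads in all, transcript levels in the starved and 6 h libraries were the most alike of the 3 pairs by point estimate. Their log2(CPM + 1) values had a Pearson correlation of 0.26 (95% bootstrap interval 0.20 to 0.30) and a Spearman correlation of 0.14 (0.09 to 0.18). For the 2 h and starved libraries these were 0.12 (0.06 to 0.17) and 0.03 (-0.01 to 0.07), and for the 6 h and 2 h libraries 0.10 (0.05 to 0.15) and 0.01 (-0.03 to 0.05). The 2 h library had 0 reads for 1168 of these contigs, against 254 in the starved and 384 in the 6 h library. Whether the starved and 6 h libraries would rank as most alike without these zeros was not tested. The 3 pairs make 6 coefficients, and contigs are not independent replicates. Contigs entered by their reads summed over the same libraries, which leaves out contigs low in all of them. The low coefficients therefore do not by themselves show that the libraries are unlike. The coefficients moved with the settings: the Pearson coefficients were 0.10, 0.04 and 0.04 in the same order with a minimum of 100 reads, and 0.39, 0.25 and 0.24 with a pseudocount of 10 CPM.

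**Figure D2:**
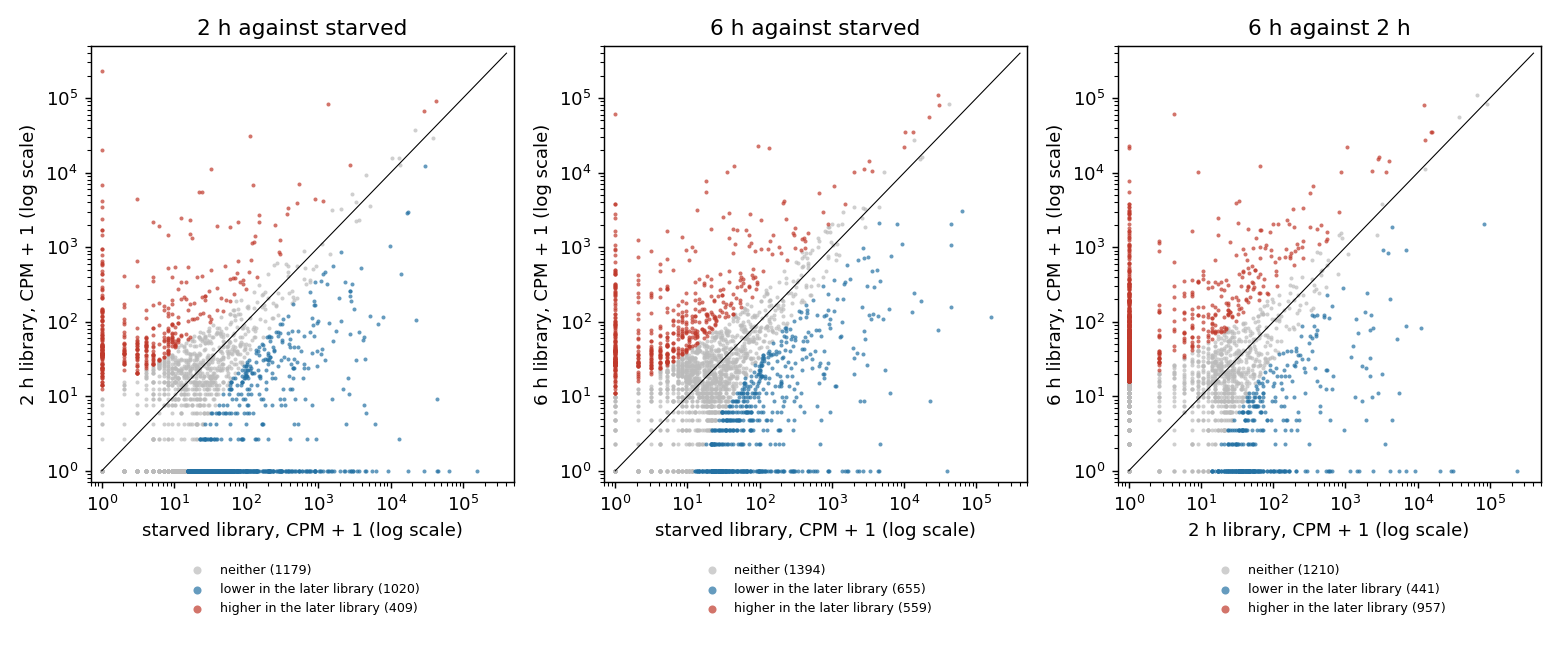
CPM + 1 of each of 2608 contigs in pairs of libraries, on log scales, with points coloured by call and the line of equal values drawn. In each of the 3 comparisons more than 1200 contigs lie beyond the limit of 2-fold, and many sit on an axis because they had 0 reads in 1 library.

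Compared with the starved library, 409 contigs were higher and 1020 were lower in the 2 h library, and 1179 were not called. Simulated libraries with no difference gave a median of 0 calls and at most 3 in either direction. The contigs with the clearest rise were ctg8463, with 143161 reads (233920 CPM) in the 2 h library and 0 in the starved library, at least 74198-fold higher, and ctg6614, with 12450 reads and 0, at least 6453-fold higher. The clearest falls were those of ctg7802, from 148896 reads (156473 CPM) to 0, at least 31921-fold lower, and of ctg9433, from 60280 reads to 0, at least 12923-fold lower. These bounds, as all those against 0 reads, limit reads and not molecules, and in the 2 h library a contig with reads had a median of 9. By prefix, 263 of 1593 ctg contigs were higher and 637 lower, and 121 of 947 rep contigs were higher and 374 lower. Of the 58216 vbc contigs listed only 68 entered, of which 25 were higher and 9 lower. The share of all reads on vbc contigs was nevertheless 1.05% in the 2 h library and 1.22% in the starved library. A rare contig could enter through the library where its reads were many, which favours a higher call there. A vbc contig with reads had a median of 6 reads in the 2 h, 2 in the starved and 3 in the 6 h library. The split among the 68 vbc contigs therefore does not describe vbc contigs in general, in any comparison. The 2 h library had 0 reads for 1168 of the 2608 contigs, against 254 in the starved library, and it was the library with the fewest contigs and the most reads per contig. When reads were divided by each library's median reads per contig before the intervals were computed, an alternative chosen after the data were seen, 169 contigs were higher and 246 lower.

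In the 6 h library 559 contigs were higher and 655 lower than in the starved library, and 1394 were not called. The clearest rises were those of ctg6999, from 0 to 48595 reads (61612 CPM), at least 19543-fold higher, and of ctg7125, from 0 to 2982 reads, at least 1199-fold higher. The clearest falls were those of ctg5510, from 36846 reads (38721 CPM) to 0, at least 10180-fold lower, and of ctg9075, from 21547 reads to 6, which was 2977-fold lower (95% interval 1367 to 8112). Among the 1593 ctg contigs 379 were higher and 426 lower, and among the 947 rep contigs 169 and 225. Of the 68 vbc contigs, 11 were higher and 4 lower. Simulated libraries with no difference gave at most 2 calls in either direction. With the reads divided as above, 325 contigs were higher and 306 lower, so the direction with more calls changed.

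Between the times after photoinduction, 957 contigs were higher and 441 lower in the 6 h library than in the 2 h library, and 1210 were not called. ctg6999 had 2 reads at 2 h and 48595 at 6 h, which was 18854-fold higher (5219 to 155684), and ctg5684 had 0 and 17795 reads, at least 4603-fold higher. ctg8463 fell from 143161 reads to 0, at least 61500-fold lower, and ctg6567 from 18711 reads to 0, at least 8038-fold lower. Among the 1593 ctg contigs 611 were higher and 266 lower, and among the 947 rep contigs 332 and 149. Of the 68 vbc contigs, 14 were higher and 26 lower. Simulated libraries with no difference gave at most 3 calls in either direction. With the reads divided as above, 244 contigs were higher and 148 lower.

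**Figure D3:**
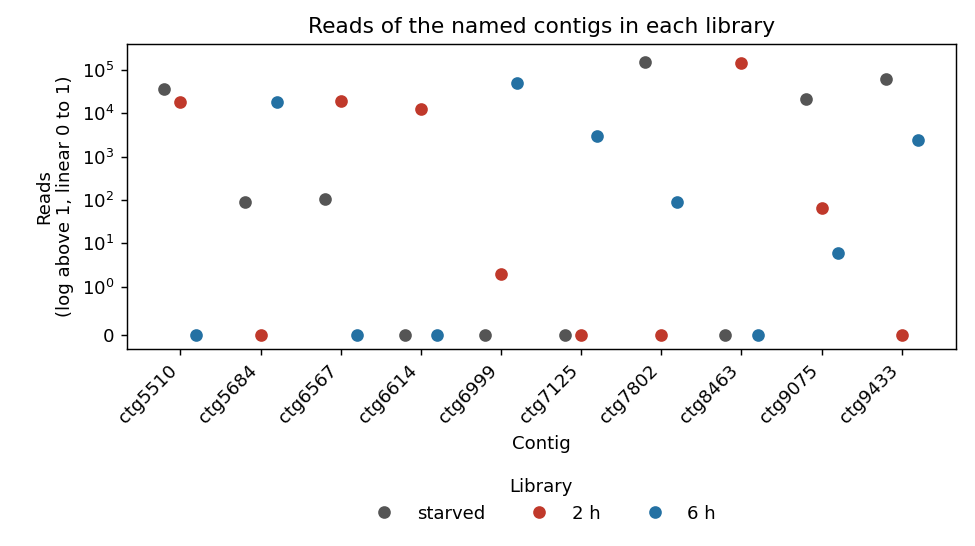
Reads of the named contigs (vertical axis, log scale above 1 and linear from 0 to 1) in the starved, 2 h and 6 h libraries, 1 point per library, without error bars. ctg8463 and ctg6614 had reads in the 2 h library only, and ctg7125 in the 6 h library only.

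Contigs followed several courses over the 3 libraries. Higher values than in the starved library at both times were called for 114 contigs and lower values at both times for 483. A further 277 contigs were called higher at 2 h and not at 6 h, and 228 of these were also lower at 6 h than at 2 h. ctg8463 and ctg6614 belong to this course. Another 479 were called lower at 2 h and not at 6 h, of which 281 were also higher at 6 h than at 2 h. At 6 h and not at 2 h, 387 contigs were called higher and 154 lower. ctg6999 and ctg7125 belong to the former course and ctg5510 to the latter, with 17675 reads at 2 h. How many of these 387 and 154 contigs also differed between 6 h and 2 h was not counted. A contig called at 6 h only is not shown to differ between the times unless its 6 h against 2 h ratio was itself called. That ratio was called for ctg6999, ctg7125 and ctg5510. Opposite directions were called for 76 contigs, 18 higher at 2 h and lower at 6 h and 58 the reverse. With the reads divided as above, 36 contigs were higher and 156 lower at both times, 127 were higher and 79 lower at 2 h and not at 6 h, so that the order of these counts turned, and 6 and 11 took opposite directions.

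Both comparisons with the starved library share that library. Independent lists of the same sizes would share 87.7 higher and 256 lower contigs, against 114 and 483 observed, and simulated libraries with no difference shared at most 1 and 0. Across contigs, the log2 ratios at 2 h and at 6 h had a Pearson correlation of 0.41 (0.37 to 0.44), which lay within the range of the simulated values, 0.32 to 0.42. Their covariance was 5.20 (4.66 to 5.76), against a simulated median of 0.10, a difference of 5.10. The simulation contained counting error only and the starved library cannot be split. Part or all of the excess in overlap and in covariance can therefore come from the shared library. These values do not show a change common to both times.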

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

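The courses of 76 contigs stood out because they were called in opposite directions at the 2 times after photoinduction: 18 were higher at 2 h and lower at 6 h than in the starved library, and 58 were lower at 2 h and higher at 6 h. These counts fell to 4 and 16 with a fold limit of 4, and to 6 and 11 with reads divided by the median reads per contig. They were 27 and 36 with a minimum of 100 reads, and 15 and 71 without a filter. Each time was represented by 1 library, so whether the effect of photoinduction differs between the times was not tested; only the reads of the libraries were compared. Among the named contigs, ctg5684 had 90 reads in the starved library, 0 at 2 h and 17795 at 6 h, at least 4603-fold higher at 6 h than at 2 h. ctg6567 took the opposite course, with 107 reads in the starved library, 18711 at 2 h and 0 at 6 h, at least 8038-fold lower at 6 h than at 2 h.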

How the results depend on the processing

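No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out as a replicate; the gene lists, and their alternatives, were not run. Total-count scaling moved the ratio of the scaled library totals, and with it the log2 ratio of contigs well above the pseudocount in both libraries, by 0.25 (2 h against starved), 0.13 (6 h against starved) and -0.12 (6 h against 2 h) relative to TMM; contigs at 0 in a library moved by other amounts. Under total-count scaling, DESeq2 size factors, the 99% interval and thinning, all 6 counts of higher and lower contigs and the 10 counts of courses stayed within 1.5 times their reported values. Turned calls were not counted for the comparison without the 2 h library. Under the other alternatives, no contig called in a comparison was called in the opposite direction. A turned call would need a ratio to move from above 2 to below the inverse of 2, so the absence of turned calls tests little. The named contigs that entered an alternative kept their calls. Thinning kept between 69.7% (lower at 2 h against starved) and 91.8% (lower at 6 h against 2 h) of the contigs in each of the 6 counts. The comparison of the starved and 6 h libraries without the 2 h library in the filter and scaling, chosen after the data were seen, gave 527 higher and 623 lower contigs. Counts in the following sentences are given as higher and lower at 2 h against starved, at 6 h against starved and at 6 h against 2 h. With a minimum of 100 reads, which leaves 819 contigs, they were 177 and 351, 240 and 297, and 347 and 194. Without a filter, with 16331 contigs, the counts that moved were 660 higher at 2 h, 1010 lower at 6 h, and 1468 and 784 between the times. With a fold limit of 4, they were 639 lower at 2 h and 352 and 421 at 6 h. With reads divided by the median reads per contig, chosen after the data were seen, they were 169 and 246, 325 and 306, and 244 and 148; the higher share of calls at 2 h was then 40.7% against 28.6%. Lower contigs at both times numbered 205 (minimum of 100 reads), 770 (no filter), 256 (fold limit of 4) and 156 (reads divided), and higher contigs at both times 53 (fold limit of 4) and 36 (reads divided). Contigs higher at 2 h and not at 6 h numbered 73 (minimum of 100), 556 (no filter) and 127 (reads divided), of which 67, 469 and 96 also fell between the times. Contigs lower at 2 h and not at 6 h numbered 110 (minimum of 100) and 79 (reads divided), of which 98 and 57 also rose between the times, as did 185 with a fold limit of 4. At 6 h and not at 2 h, 127 were higher and 65 lower with a minimum of 100, and 651 were higher without a filter. Opposite courses, higher then lower and lower then higher, numbered 4 and 16 (fold limit of 4) and 6 and 11 (reads divided), and 36 contigs were lower then higher with a minimum of 100. The correlation of the log2 ratios at 2 h and 6 h was 0.49 without a filter and 0.47 with a pseudocount of 10 CPM, and their covariance was 9.21 (minimum of 100), 2.44 (no filter), 2.34 (pseudocount of 10) and 6.38 (without the 10 most abundant contigs of each library). Pearson correlations of the 2 h and starved, 6 h and starved, and 6 h and 2 h libraries were 0.039, 0.095 and 0.039 with a minimum of 100, 0.25, 0.39 and 0.24 with a pseudocount of 10, and 0.059, 0.18 and 0.036 without the most abundant contigs; the Spearman correlation of the 6 h and starved libraries was 0.025 with a minimum of 100. Contigs with 5 or more reads numbered 4110 in the starved and 3889 in the 6 h library, against 2194 in the 2 h library; at equal totals they numbered 2576, 2972 and 2194. The filters changed the TMM factors as well as the number of contigs. For the starved and 2 h libraries the factors were 0.917 and 1.09 in the main setting. They were 0.782 and 1.28 without a filter, and 1.06 and 0.791 with a minimum of 100 reads. Counts under these filters therefore differ from the reported ones in scaling and in contigs together. How much each contributed was not tested, nor were other causes of these changes. In the simulated data of 2608 contigs, 4-fold falls were called less often than 4-fold rises at these depths, for example 44.0% against 78.0% for the 6 h against the starved library.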

Other observations

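The tests of reads on rare contigs, of abundant contigs missing at 2 h and of absence by library were chosen after the results they measure had been seen; the other tests were set out before.

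The 2 h library had reads on 3076 contigs, fewer than the other libraries. A lower total does not account for this, since the starved and 6 h libraries thinned to the 2 h total still had at least 2.67 times as many contigs with 1 or more reads. Counted from 5 reads, the difference at equal totals was smaller, with 2576 contigs in the starved, 2972 in the 6 h and 2194 in the 2 h library, so a lower total is excluded only for the contigs counted from 1 read. Counted from 1 read, the share of reads taken by the most abundant contigs does not account for it either: after removal of the 10 most abundant of each library (21 in all) and thinning to 164673 reads, the ratio was still at least 2.38. It stays open whether fewer distinct molecules entered the amplification and gave more reads each. Contigs with 1 to 3 reads in both other libraries at equal totals had, where detected, a median of 7 reads in the 2 h library. This was 2.33 times the highest such median of the others (3 at 6 h, 2 in the starved library). By the same rule, 13.9% of such contigs had reads in the 2 h, 52.1% in the starved and 49.7% in the 6 h library. However, fewer contigs at an equal total leave more reads to each on average, whatever the cause. Whether rare contigs would follow that average was not tested. A loss of transcripts 2 h after photoinduction stays open as well: 42 of 171 contigs with at least 100 reads in both other libraries (24.6%, exact interval 18.3 to 31.7) had 0 reads at 2 h, against 5 of 87 in the starved and 9 of 100 in the 6 h library by the same rule, and with 1 library for this time these explanations cannot be told apart.

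Among all pairs of libraries there were 90 cases of a contig with at least 1000 reads in a library and 0 in another. Counting error of reads at these totals does not account for them, since the highest number in 100 draws of reads from a single profile was 0; sampling of molecules before amplification was not tested by these draws. Of the contigs with at least 1000 reads in the starved library 30.9% had 0 reads at 2 h and 11.3% at 6 h, and of those in the 6 h library 32.9% had 0 at 2 h and 9.21% in the starved library, shares that differ by at least 2.73 times. A lower number of distinct molecules and a loss of transcripts at 2 h both predict more absences there, so they cannot be told apart for these cases either. The other 35 cases did not involve absence from the 2 h library, and neither a biological change nor uneven amplification of single contigs was tested for them.

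Some contigs had nearly the same ratios in both comparisons, such as ctg5263 (16632, 1804 and 12603 reads in the starved, 2 h and 6 h libraries) and ctg5515 (15861, 1739 and 11955), which were picked after their values were seen. The hypothesis that many contigs carry reads of the same transcript was tested on the 68 contigs with at least 100 reads in every library: 3 pairs matched within 0.1 log2 units in both ratios, against a median of 3 and a highest count of 10 in 10000 permutations. The number of matched pairs was thus no higher than chance pairing gives, which says nothing about any single pair. Near the limit of 100 reads, counting error in a ratio can exceed the tolerance of 0.1 log2 units. Pieces of the same transcript could then fail to match, and how often they would was not measured. The count of pairs therefore does not exclude split transcripts.

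In each of the 6 directions between libraries at least 1 contig with 10000 or more reads in a library had 0 reads in the other; the least stringent limit this sets on carry-over is 0.0169% (ctg5684, 17795 reads at 6 h and 0 at 2 h, with 0 counted as 3 reads).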
